A study of Glycine max with 44 samples.

How the data were processed

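Root RNA of 2 soybean genotypes was measured on 44 Affymetrix soybean arrays. PI416937 is the aluminium-tolerant genotype and Young the aluminium-sensitive genotype of the series. Plants were grown in hydroponics with 10 µM Al or with 0 µM Al, and roots were sampled at 2, 12, 48 and 72 h. These factors give 16 groups, with 2 arrays per group at 2 h and 3 arrays per group at 12, 48 and 72 h. The number of arrays limits the precision of every value. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples.

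The deposited table holds, for each probe set and array, an intensity on a linear scale, which the authors had already brought to a common scale across arrays. How the authors summarised, background-corrected and normalised the arrays: Not given in the sources used here. Array medians of all 61170 probe sets lay between 6.56 and 7.52 intensity units, and the lowest intensity was 3.22. Of these probe sets, 37593 were taken as soybean. Another 15820 target the oomycete Phytophthora sojae and 7530 the nematode Heterodera glycines. Those 23350 probe sets should find little target in uninfected roots, and they set the background. A further 227 control probe sets, 48 of them soybean rRNA controls, were left out of the tests. Adding the 47 rRNA controls that pass the filter was tried as an alternative.

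Intensities were transformed as log2(intensity + 16), so differences of dim genes are understated relative to fold changes of raw intensity. The background was the 95th percentile of the means of the probe sets of other organisms, at 4.41 log2 units. A soybean probe set was tested when its mean in at least 1 of the 16 groups exceeded that level, which kept 35289 probe sets. Medians of the tested probe sets ranged over 0.138 log2 units between arrays, under the limit of 0.2 set for quantile normalisation, so none was applied. No pair of arrays was identical, the highest correlation between arrays being 0.9982. Signal over background is the limit of depth here: groups whose means both lie near 4.41 are within background.

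Group means were fitted with limma 3.58.1 in R 4.3.3, with lmFit on 16 group means over all 44 arrays, contrasts, and eBayes with a trend. The fit had 28 residual and 1.94 prior degrees of freedom. There were 16 comparisons. They are treated minus untreated in each genotype at each time and as the mean of the 4 times, PI416937 minus Young for each of those responses, and PI416937 minus Young in untreated roots as the mean of the 4 times. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05. Values after ± are standard errors of the limma contrast unless SD is given. They and the p-values rest on a single spread per probe set, pooled over the 16 groups. Where most groups lie at background, this can understate the spread of a group far above it. The test, the filter, the alternatives, the gene lists described as fixed and the rule for naming genes were chosen before the data were examined.

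Of the tested probe sets, 8418 had a single annotated gene, covering 5887 genes, and 26871 had none, so most counts of probe sets cannot be resolved to genes. Only 959 of those genes had a symbol other than a locus number. Genes were named by a rule: the 10 highest and the 10 lowest differences among called probe sets with an annotated gene, plus up to 4 members of each list with the smallest p, in rank order and stopping early. A gene with several probe sets was represented by that with the smallest p. Where a count of its probe sets follows, it counts those called in the same direction, and the size is of the representing one. Gene positions are those of the assembly Glycine_max_v4.0 of the cultivar Williams 82.

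There were 30 gene lists fixed as patterns. They were planned for symbols or descriptions, but only gene symbols and synonyms were searched, so genes known by a description alone were missed. Of these lists, 9 had no measured member, among them those for peroxidases, callose, ABC transporters and vascular markers. A further 19 lists were written after the annotation table had been seen and before any comparison. They are called added lists. Lists with at least 5 probe sets were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation. For the fixed lists this gave 13 lists in 12 comparisons, or 156 tests. List members called were counted over all tested probe sets and also adjusted over the list alone. The preset correlation gave 55 calls among the 156 camera tests. With an estimated correlation camera gave 0 calls, with 15 tests at an unadjusted p under 0.05 and a smallest adjusted p of 0.0743.

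Whether replicate numbers pair treated with untreated arrays was checked by correlating residuals within groups. The numbers paired the arrays in Young at 12 h (correlations 0.24 to 0.29) and at 48 h (0.38 to 0.48), above the limit of 0.1, and a fit with the 22 pairs as blocks was run for all comparisons. At 2 h only 2 pairs exist per genotype, which cannot be judged. Sample codes follow each other in 6 runs, which could not be tied to dates or batches, and the arrays of 72 h form runs of their own in each genotype. Other alternatives were a block for these runs, eBayes without trend, no filter, a filter at the 99th percentile (4.52 log2 units, 32877 probe sets), quantile normalisation, fits on the compared groups alone, array weights, log2(intensity + 1), leaving out each array, and a 2-fold threshold. The procedure was tested on simulated data with 40 changed probe sets per size. At a difference of 2 log2 units it recovered 80% in the Young 48 h comparison with 3 false calls, and 72.5% in the 72 h comparison of responses with 4 false calls. The simulation drew independent residuals, without pairing, correlated probe sets or outlying arrays, and changed only brighter probe sets. Its false calls are thus no measure of those in the real arrays.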

Results

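The series asks how roots of an Al-tolerant and an Al-sensitive soybean change their transcripts under Al. Its 44 arrays fall into 16 groups of genotype, treatment and time. Each group at 2 h holds 2 arrays, and each group at 12, 48 and 72 h holds 3. All differences are on the scale log2(intensity + 16) from the deposited normalised intensities, with background at 4.41. They were tested with limma. Differences from a group mean at or under background are lower limits: LOC100804226, PIP2-8 and EXP2 in PI416937 at 2 h (untreated 4.40, 4.37 and 4.38), WRKY21 in Young at 48 h (4.41), and WRKY30 and LOC100527097 in Young at 72 h (4.40 and 4.36). Means over times and differences in response that use such group means are not exact either, as for PIP2-8 at 2 h, LOC547562 at 48 h, WRKY30 at 72 h, and PIP2-8 and WRKY30 as the mean of the 4 times. The probe set given for CHS1, G4DT, GSTU41, CYP82A2, CYP82A3 and SFERH-2 is not the same in every comparison, so their sizes are not to be set against each other. For every gene named in a comparison of treated with untreated roots within a genotype and time, all treated arrays lay on the same side of all untreated arrays, which choosing genes by the test favours and is no separate evidence. The plot of called probe sets gives the counts of all 16 comparisons.

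**Figure D1:**
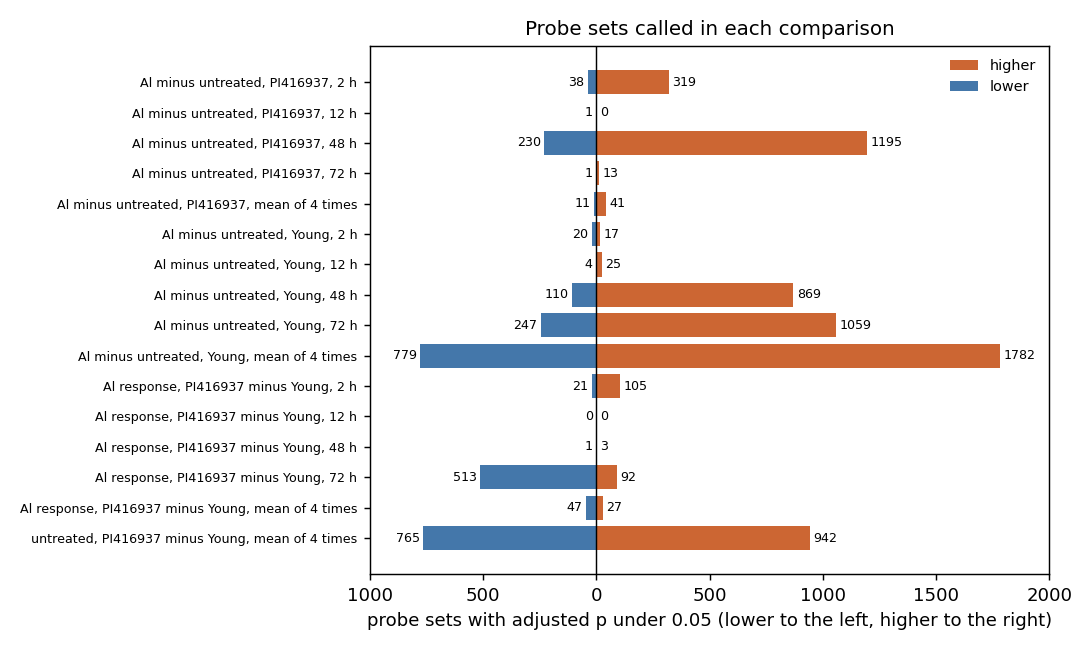
Bars give the number of probe sets with an adjusted p under 0.05 in each of the 16 comparisons, higher to the right of 0 and lower to the left, on a linear axis counting probe sets. Treated minus untreated counts in PI416937 reach 1425 at 48 h and 14 at 72 h, and in Young they are 979 at 48 h and 1306 at 72 h.

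The first comparison asks what 2 h of Al changed in PI416937. The glyoxylate cycle enzymes malate synthase (MS) and isocitrate lyase (ICL1) rose by 5.11 ± 1.07 and 3.17 ± 0.63 log2 units (adjusted p = 0.00808 and 0.00529, n = 2 per group). MS went from 4.98 ± 0.83 (SD) in untreated roots to 10.08 ± 0.08 (SD) with Al. The plasma membrane aquaporin PIP2-8, on chromosome 19 from 44449696 to 44451965, rose by 3.82 ± 0.27 from background (adjusted p = 1.62e-11), and both of its probe sets were called. With single arrays left out the difference of PIP2-8 lay between 2.83 and 4.8, so the pooled standard error understates the spread of its treated arrays. The uncharacterised loci LOC100804226, LOC100779901, LOC100305932 and LOC100794412 rose by 6.58 ± 1.23, 5.03 ± 1.22, 4.71 ± 1.19 and 4.66 ± 0.42. Their adjusted p were 0.00244, 0.0316, 0.0438 and 1.06e-08. LOC100305764 fell by 1.09 ± 0.26 (adjusted p = 0.0244).

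Of 32 aquaporin probe sets in 17 genes, 2 were higher and 0 lower, or 3 higher adjusted over the list alone. The camera call for that list (adjusted p = 0.00171) was lost, with adjusted p = 0.192 with an estimated correlation. Among the 239 probe sets of WRKY, NAC and MYB transcription factors, 7 were higher and 0 lower, or 9 and 0 adjusted over the list alone. Camera gave them an adjusted p = 0.0108, and adjusted p = 0.69 with an estimated correlation. The examples MYB118 and MYB109 rose by 2.03 ± 0.42 and 1.71 ± 0.31 (adjusted p = 0.00695 and 0.00217). Of 7 cell wall probe sets 1 was higher, for the expansin EXP2 with 0.93 ± 0.20 (adjusted p = 0.013), and 3 were higher adjusted over the list alone. That list had a camera adjusted p = 0.00805, and adjusted p = 0.174 with an estimated correlation. The 21 heat shock and chaperone probe sets had 0 calls by limma over all tested probe sets and 0 adjusted over the list alone, with a median of -0.61. The camera call downward (adjusted p = 0.00163) was lost at adjusted p = 0.329 with an estimated correlation. The 5 probe sets of the photosynthesis list, meant to mark light-exposed tissue, were all of 1 gene. They had 0 calls over all and 1 adjusted over the list alone, with a median of 1.95. Camera gave them an adjusted p = 0.0127, and adjusted p = 0.174 with an estimated correlation.

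At 2 h in PI416937, limma called 357 of 35289 probe sets, 319 higher and 38 lower, and 212 of them changed at least 2-fold. The count was 184 without treated replicate 2, 717 without untreated replicate 1 and 893 without treated replicate 1. Leaving out treated replicate 2 ended 8 of the 11 named calls, untreated replicate 2 ended 7, untreated replicate 1 ended 4 and treated replicate 1 ended 3. Without treated replicate 2 the difference of LOC100804226 was 4.28, from treated arrays with an SD of 3.25, and that of EXP2 was 0.45 (1.42 without treated replicate 1). With pairs as blocks MS, LOC100779901 and LOC100305932 lost their calls (adjusted p = 0.0582, 0.0544 and 0.0847). A fit on the compared groups alone called 0 probe sets by limma, which ended all 11 named calls, with 1719 at an unadjusted p under 0.05.

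At 12 h of Al in PI416937, no annotated gene passed the test. The single call was a probe set without an annotated gene, described here after its values were seen. It fell by 1.09 ± 0.17 (adjusted p = 0.0219), from 5.77 ± 0.69 (SD, n = 3) to 4.68 ± 0.19 (SD, n = 3). WRKY, NAC and MYB factors had 0 calls, 0 also adjusted over the list alone, and a camera adjusted p = 0.0116 upward. This became adjusted p = 0.719 with an estimated correlation. Glutathione S-transferases (GST), enzymes of detoxification, had 0 calls in 57 probe sets over all and adjusted over the list alone. Their camera adjusted p = 0.000476 became adjusted p = 0.719 with an estimated correlation. Limma gave 1584 probe sets at an unadjusted p under 0.05. The count was 0 without treated replicate 1, 0 without untreated replicate 2, 2 without treated replicate 2, 6 without untreated replicate 1, 7 without treated replicate 3 and 91 without untreated replicate 3. That array had a mean of 7.72 over the 637 probe sets called higher with Al at 48 h in both genotypes, against 6.96 and 6.54 in the other untreated arrays, with WRKY30 at 6.69.

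After 48 h, Al had the largest count of calls of any single time in PI416937. WRKY30, a transcription factor gene on chromosome 17 from 37443032 to 37448059, rose by 5.60 ± 0.63 log2 units (adjusted p = 8.39e-06). Its level went from 4.48 ± 0.10 to 10.08 ± 1.12 (SD, n = 3 each), and both probe sets were called. WRKY17, WRKY57 and WRKY58 rose by 5.30 ± 0.74, 4.48 ± 0.50 and 4.36 ± 0.57 (adjusted p = 0.000117, 8.39e-06 and 5.64e-05). Of the 239 WRKY, NAC and MYB probe sets 38 were higher and 0 lower, or 63 and 1 adjusted over the list alone. Camera gave an adjusted p = 4.42e-15, and adjusted p = 0.228 with an estimated correlation. The uncharacterised LOC100500298 rose by 5.81 ± 0.94 (adjusted p = 0.000429).

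Some defence and detoxification genes were also called at 48 h in PI416937. Of 57 GST probe sets, 9 were higher and 1 lower, or 12 and 2 adjusted over the list alone, with a camera adjusted p = 0.00999 and adjusted p = 0.549 with an estimated correlation. GSTU41 and LOC547581, also named GSTU21, rose by 3.20 ± 0.80 and 3.24 ± 0.84 (adjusted p = 0.0177 and 0.0229), whereas GSTF7 fell by 2.06 ± 0.53 (adjusted p = 0.0213). Of 29 phenylpropanoid and isoflavonoid probe sets, 4 were higher and 0 lower, or 5 adjusted over the list alone, without a camera call (adjusted p = 0.303). The list median of -0.01 and its mean of 0.27 differ in sign. Chalcone synthase CHS1, which starts flavonoid synthesis, rose by 1.93 ± 0.48 in 3 of 7 probe sets (adjusted p = 0.0178). Isoflavone synthase IFS2 rose by 1.24 ± 0.32 (adjusted p = 0.0227), and G4DT, a prenyltransferase of glyceollin synthesis, by 3.70 ± 0.94 (adjusted p = 0.0204). Of 7 pathogenesis-related probe sets, PR1-7 was higher by 2.13 ± 0.59 (adjusted p = 0.0338). That list gave 1 call over all and 4 adjusted over the list alone, with a camera adjusted p = 0.00802 and adjusted p = 0.382 with an estimated correlation. Of 68 cytochrome P450 probe sets, which include cyclophilins caught by the pattern, 4 were higher and 2 lower, and the same numbers held adjusted over the list alone. CYP82A3 rose in 3 of 4 probe sets, by 2.91 ± 0.75 in the one chosen (adjusted p = 0.0217) and by 5.07 in the one given for Young at 48 and 72 h (adjusted p = 0.025).

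In the added lists of the same comparison, a minority of probe sets was called. The ferritin SFERH-2, an iron storage protein, rose by 3.53 ± 0.92 in 3 of 4 probe sets (adjusted p = 0.0244), and gave the 3 calls of 16 probe sets of ferritins and metal carriers, or 4 adjusted over the list alone. The median of that list, -0.08, and its mean, 0.73, differ in sign. The SWEET sugar transporters gave 2 calls of 7 probe sets, over all and adjusted over the list alone, SWEET34 with 2.38 ± 0.47 and SWEET29 with 2.40 ± 0.63 (adjusted p = 0.00268 and 0.0252). DREB2A2, of 2 calls in 16 DREB and ERF probe sets over all and adjusted over the list alone, rose by 2.82 ± 0.55 (adjusted p = 0.00244), and the heat shock factor HSF-14, of 2 calls in 14 or 5 adjusted over the list alone, by 1.29 ± 0.34 (adjusted p = 0.0277). Camera gave the DREB and ERF list an adjusted p = 0.0205, and adjusted p = 0.39 with an estimated correlation. The heat shock factors had a camera adjusted p = 0.00779, and the adjusted p = 0.39 with an estimated correlation.

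Among genes that fell at 48 h in PI416937 were the lipoxygenase LOX10, by 2.59 ± 0.57 (adjusted p = 0.0065), and allene oxide synthase CYP74A1, an enzyme of jasmonate synthesis, by 1.16 ± 0.32 (adjusted p = 0.0313). Of 27 jasmonate and lipoxygenase probe sets 0 were higher and 1 lower, and also 0 and 1 adjusted over the list alone. Camera gave an adjusted p = 0.0122 downward, and adjusted p = 0.404 with an estimated correlation. LOC100792188, LOC100137082, LOC100778626 and AS2 fell by 4.56 ± 0.81, 4.05 ± 1.09, 2.65 ± 0.64 and 2.54 ± 0.51 (adjusted p = 0.00101, 0.0277, 0.0131 and 0.00302). The 8 probe sets of the organic acid list, all of phosphoenolpyruvate carboxylase genes, had 0 calls by limma over all and 0 adjusted over the list alone. Their camera adjusted p = 0.0161 downward became adjusted p = 0.382 with an estimated correlation.

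Limma called 1425 probe sets at 48 h in PI416937, 1195 higher and 230 lower, of which 1074 changed at least 2-fold, with 6420 at an unadjusted p under 0.05. The count was 492 without treated replicate 2, 624 without untreated replicate 3 and 931 without treated replicate 1. A fit on the compared groups alone called 246 and ended 18 of the 24 named calls, with LOC100792188, AS2, SWEET34 and DREB2A2 among them (adjusted p of up to 0.212). Of the 24 named calls, 12 ended without treated replicate 2 and 12 without untreated replicate 3. Another 11 ended without untreated replicate 2, 10 without treated replicate 1, 6 without untreated replicate 1 and 3 without treated replicate 3. WRKY30, WRKY17, WRKY57, WRKY58, LOC100500298, LOC100792188, LOX10, AS2, SWEET34 and DREB2A2 kept their calls without each of the 6 arrays. The 3′ to 5′ ratio of the glutathione transferase control was lower with Al by 0.59 without overlap (two-sided exact permutation p = 0.1, the smallest possible). With pairs as blocks, CYP74A1 and G4DT lost their calls, with adjusted p of up to 0.0657.

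At 72 h of Al in PI416937 the called differences were small and close to background. LOC100809384 rose by 0.46 ± 0.07, from 4.43 ± 0.01 to 4.89 ± 0.16 (SD, n = 3 each, adjusted p = 0.00312). LOC100527539 rose by 0.19 ± 0.03 (adjusted p = 0.000433). No WRKY, NAC or MYB probe set was called, over all or adjusted over the list alone, and their camera adjusted p = 1.1e-06 downward became adjusted p = 0.706 with an estimated correlation. WRKY30 lay at 7.85 in untreated replicate 1 and at 4.43 and 4.46 in the other untreated arrays. Limma called 14 probe sets, 13 higher and 1 lower, and 0 of them changed at least 2-fold, with 904 at an unadjusted p under 0.05. The count was 26 without untreated replicate 2, 27 without treated replicate 1, 61 without treated replicate 3, 68 without treated replicate 2 and 7 with pairs as blocks, where LOC100527539 lost its call (adjusted p = 0.0593).

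As the mean of the 4 times in PI416937, the named genes were also called at 2 h. LOC100794412 and PIP2-8 rose by 1.19 ± 0.18 and 0.96 ± 0.11 (adjusted p = 0.000736 and 8.73e-06). These means rest mainly on 2 h, where the differences were 4.66 and 3.82. Of 32 aquaporin probe sets 1 was higher, and 1 adjusted over the list alone, without a camera call (adjusted p = 0.153). Limma called 52 probe sets, 41 higher and 11 lower, with 4 of them at least 2-fold. The count was 32, 391 and 34 without untreated replicate 3 of 72 h, untreated replicate 1 of 72 h and untreated replicate 2 of 48 h. It was 34 and 168 without untreated replicates 2 and 3 of 12 h, 204 and 86 without untreated replicates 1 and 2 of 2 h, and 577 and 79 without treated replicates 1 and 2 of 2 h.

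In Young, 2 h of Al changed few annotated genes. LOC778176, also named MYB88, rose by 1.06 ± 0.23 from a level near background (adjusted p = 0.0497, n = 2 per group), and LOC100779715 fell by 0.80 ± 0.17 (adjusted p = 0.0433). The MYB gene was the single call among WRKY, NAC and MYB factors, over all and adjusted over the list alone. The heat shock and chaperone list had 0 limma calls over all and 1 higher adjusted over the list alone, with a median of 0.48 and a camera adjusted p = 3.44e-09 upward. That became adjusted p = 0.194 with an estimated correlation. The 3′ to 5′ ratio of the actin control probe sets differed by -0.22 log2 units with Al, without overlap of the groups (two-sided exact permutation p = 0.333, the smallest possible with 2 against 2). That of the glutathione transferase control was 0.58 ± 0.46 with Al and 0.35 ± 0.25 without (SD), the other way. Limma called 37 probe sets, 17 higher and 20 lower, 9 of them at least 2-fold. The count was 63 without treated replicate 1, 77 without untreated replicate 1, 202 without untreated replicate 2 and 278 without treated replicate 2. Both named calls ended without untreated replicate 1, and 1 of them without each of the other 3 arrays. Both also ended with pairs as blocks (adjusted p of up to 0.141) and without the variance trend (up to 0.0768). LOC778176 stood at 0.47 and 1.66 without treated replicates 1 and 2, and LOC100779715 at -0.42 without treated replicate 2.

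At 12 h in Young, 4 WRKY genes were among the calls. WRKY30 rose by 3.60 ± 0.63 (adjusted p = 0.0123), from 4.65 ± 0.20 to 8.25 ± 1.19 (SD, n = 3 each). WRKY57, on chromosome 18 from 50298774 to 50300765, rose by 3.42 ± 0.50 (adjusted p = 0.00248), and WRKY43 and WRKY58 by 3.20 ± 0.64 and 2.88 ± 0.57 (adjusted p = 0.0344 and 0.034). Of the 239 WRKY, NAC and MYB probe sets 4 were higher and 0 lower, or 11 and 1 adjusted over the list alone. Camera gave an adjusted p = 0.00586, and adjusted p = 0.811 with an estimated correlation. LOC100793962 and LOC547561 rose by 3.72 ± 0.77 and 3.29 ± 0.61 (adjusted p = 0.0498 and 0.0174), and LOC100306243 fell by 2.25 ± 0.44 (adjusted p = 0.0339).

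Replicate numbers pair the arrays of this comparison, and the fit with pairs as blocks called 8 probe sets against 29 (25 higher, 4 lower) without blocks. WRKY57 and LOC100306243 kept their calls with blocks (adjusted p = 0.0135 and 0.0271). The calls of WRKY30, LOC547561, WRKY58, WRKY43 and LOC100793962 ended (adjusted p = 0.0562, 0.0562, 0.0629, 0.0703 and 0.083). Without blocks, the count was 2 without treated replicate 2, which ended all 7 named calls. It was 16 without untreated replicate 1, 16 without untreated replicate 3, 51 without treated replicate 1, 143 without untreated replicate 2 and 969 without treated replicate 3. These left-out arrays ended 5, 6, 5, 2 and 0 of the 7 named calls, and a limma fit on the compared groups alone, with 0 calls and 1134 at an unadjusted p under 0.05, ended all 7.

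After 48 h of Al, WRKY30 in Young rose by 6.26 ± 0.63 (adjusted p = 1.02e-06), from 4.47 ± 0.03 to 10.73 ± 0.45 (SD, n = 3 each). WRKY17, WRKY57 and WRKY21 rose by 5.54 ± 0.74, 4.86 ± 0.50 and 3.55 ± 0.45 (adjusted p = 3.7e-05, 1.13e-06 and 2.78e-05). Of the 239 WRKY, NAC and MYB probe sets 27 were higher and 0 lower, or 51 and 1 adjusted over the list alone. The list had a camera adjusted p = 5.94e-11, and adjusted p = 0.268 with an estimated correlation. The uncharacterised LOC100795901 and LOC100306181 rose by 5.98 ± 1.07 and 5.97 ± 1.07 (adjusted p = 0.00109 and 0.00117).

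Some detoxification, isoflavonoid and defence genes were called in Young at 48 h. Of 57 GST probe sets 8 were higher and 0 lower, or 15 and 0 adjusted over the list alone, with a camera adjusted p = 4.23e-08 and adjusted p = 0.316 with an estimated correlation. GSTU43, GSTU41 and LOC547581 rose by 3.11 ± 0.58, 3.05 ± 0.72 and 3.45 ± 0.84 (adjusted p = 0.0018, 0.0137 and 0.0174). Of 29 phenylpropanoid and isoflavonoid probe sets 3 were higher, or 5 adjusted over the list alone, with a camera adjusted p = 0.0182 and adjusted p = 0.327 with an estimated correlation. IFS2 rose by 1.48 ± 0.32, CHS1 by 2.53 ± 0.60 in 2 of 7 probe sets, and G4DT by 2.82 ± 0.65 (adjusted p = 0.00641, 0.0141 and 0.0118). Of 68 P450 probe sets 8 were higher and 1 lower, over all and adjusted over the list alone, without a camera call (adjusted p = 0.0652). They include CYP93A1 of the glyceollin pathway with 3.79 ± 0.92, CYP82A3 with 5.49 ± 1.34 and CYP82A2 with 4.59 ± 1.23 (adjusted p = 0.0161, 0.0172 and 0.0341). Of 7 pathogenesis-related probe sets 2 were higher, or 5 adjusted over the list alone, with PR1-7 at 2.62 ± 0.59 and PR10 at 2.68 ± 0.68 (adjusted p = 0.00933 and 0.0226). Camera gave them an adjusted p = 1.22e-05, and adjusted p = 0.125 with an estimated correlation.

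In the added lists at 48 h in Young, ferritin SFERH-2 rose by 4.43 ± 0.92 in 4 of 4 probe sets (adjusted p = 0.00471), which were the 4 calls among ferritins and metal carriers, or 4 higher and 1 lower adjusted over the list alone. SWEET34 rose by 1.93 ± 0.47 (adjusted p = 0.0182), the single call of 7 SWEET probe sets, or 2 adjusted over the list alone, whose median of -0.65 and mean of 0.14 differ in sign. HSF-14 rose by 1.23 ± 0.34 (adjusted p = 0.0451), the single call of 14 heat shock factor probe sets, or 4 adjusted over the list alone, and quantile normalisation ended it. The list had a camera adjusted p = 0.00498, and adjusted p = 0.305 with an estimated correlation. Among genes that fell were CYP74A1, by 1.28 ± 0.32, and LOC100785506, by 1.78 ± 0.44 in 1 of 4 probe sets (adjusted p = 0.0186 and 0.021). The organic acid list had 0 calls by limma over all and adjusted over the list alone, and a camera adjusted p = 0.0408 downward that became adjusted p = 0.318 with an estimated correlation.

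Limma called 979 probe sets at 48 h in Young, 869 higher and 110 lower, 819 of them at least 2-fold. With pairs as blocks, which replicate numbers support here, it called 1196, and CYP74A1 and CYP82A2 lost their calls (adjusted p = 0.0529 and 0.0733). The count was 407 without treated replicate 2, 565 without untreated replicate 1 and 587 without untreated replicate 3. A fit on the compared groups alone called 463 and ended 13 of the 22 named calls, with LOC100795901 and GSTU43 among them (adjusted p of up to 0.228). Of the 22 named calls, treated replicates 2, 3 and 1 left out ended 14, 5 and 2, and untreated replicates 2, 3 and 1 left out ended 9, 8 and 6. WRKY30, WRKY17, WRKY57, WRKY21, LOC100795901, LOC100306181 and GSTU43 kept their calls without each array. The 3′ to 5′ ratio of the glutathione transferase control was lower with Al by 0.77 without overlap (two-sided exact permutation p = 0.1, the smallest possible). Of the higher probe sets, 637 were called higher in both genotypes at 48 h, against 29.4 by independence. Of the lower ones, 28 were shared against 0.717 by independence (Fisher's exact p = 7.89e-37). That test counts probe sets that change together, and several of a gene, as independent, so its p can be far too small.

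At 72 h Young had large changes of defence genes. PR-10, also named SAM22, on chromosome 7 from 42656819 to 42657703, was higher with Al by 8.17 ± 1.60 (adjusted p = 0.00298), at 12.68 ± 1.05 against 4.51 ± 0.01 untreated (SD, n = 3 each). In untreated Young roots PR-10 lay at 11.85 and 9.19 at 2 h and at 13.09, 10.77 and 7.51 at 12 h. Treated Young roots held 13.95 and 10.23 at 2 h. The difference of PR-10 at 72 h thus rests on a low untreated level of that time as well as a high treated one. PR1-7 rose by 3.66 ± 0.59 (adjusted p = 0.000502). Of 7 pathogenesis-related probe sets 3 were higher, or 5 adjusted over the list alone, with a camera adjusted p = 4.43e-06 and adjusted p = 0.0936 with an estimated correlation. LOC547527 and LOC100527097 rose by 7.38 ± 1.50 and 7.16 ± 1.37 (adjusted p = 0.00421 and 0.00243). Of 57 GST probe sets 11 were higher, or 17 adjusted over the list alone, with a camera adjusted p = 9.86e-12 and adjusted p = 0.155 with an estimated correlation. GSTU42, GSTU47 and LOC547581 rose by 6.01 ± 1.18, 5.50 ± 1.12 and 4.13 ± 0.84 (adjusted p = 0.00298, 0.0044 and 0.00421). Of the 239 WRKY, NAC and MYB probe sets 22 were higher, or 34 adjusted over the list alone, with a camera adjusted p = 2.67e-08 and adjusted p = 0.259 with an estimated correlation. WRKY30, WRKY57 and MYB73 rose by 5.67 ± 0.63, 4.71 ± 0.50 and 3.77 ± 0.54 (adjusted p = 2.71e-06, 1.33e-06 and 0.000128).

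At 72 h in Young, 11 of 68 P450 probe sets were higher, or 14 higher and 2 lower adjusted over the list alone, with a camera adjusted p = 0.00208 and adjusted p = 0.155 with an estimated correlation. CYP82A3, on chromosome 13 from 15922866 to 15926005, rose by 6.59 ± 1.34, CYP82A2 by 6.22 ± 1.22 and CYP93A1 by 4.36 ± 0.92 (adjusted p = 0.00412, 0.00309 and 0.00529). Of 29 phenylpropanoid and isoflavonoid probe sets 3 were higher, or 7 adjusted over the list alone, with a camera adjusted p = 0.00507 and adjusted p = 0.35 with an estimated correlation. CHS1 rose by 2.27 ± 0.59 in 2 of 7 probe sets and IFS2 by 1.18 ± 0.32 (adjusted p = 0.0256 and 0.0327). In the added list of isoflavonoid and phenylpropanoid symbols 10 of 95 probe sets were higher, or 19 adjusted over the list alone, with PTS1 at 4.34 ± 0.88 (adjusted p = 0.00399). That list had a camera adjusted p = 4.88e-05, and adjusted p = 0.398 with an estimated correlation. Of 27 jasmonate and lipoxygenase probe sets 3 were higher, or 5 adjusted over the list alone, with LOX7 at 1.76 ± 0.45 (adjusted p = 0.0236). Camera gave them an adjusted p = 0.00926, and adjusted p = 0.35 with an estimated correlation.

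Of the other groups at 72 h in Young, ferritins and metal carriers gave 5 higher calls of 16 probe sets, or 5 higher and 1 lower adjusted over the list alone, with SFERH-2 rising by 5.41 ± 0.98 (adjusted p = 0.00153). Camera gave that list an adjusted p = 0.000965, and adjusted p = 0.284 with an estimated correlation. HSF-01 rose by 2.96 ± 0.72 (adjusted p = 0.0156), with 2 calls of 14 heat shock factor probe sets over all and adjusted over the list alone, a camera adjusted p = 0.00187 and adjusted p = 0.296 with an estimated correlation. CRK39, a cysteine-rich receptor-like kinase, rose by 4.07 ± 0.88 (adjusted p = 0.00644), in an added list with 4 higher calls of 26, or 5 higher and 2 lower adjusted over the list alone, whose median of -0.07 and mean of 0.28 differ in sign. EREBP1, an ethylene-responsive factor, rose by 1.68 ± 0.32 (adjusted p = 0.00267). The ethylene list had 2 calls of 14 over all and 2 adjusted over the list alone, a median of -0.07, a mean of 0.17 and no camera call (adjusted p = 0.364). The beta-tubulin TUBB3 fell by 0.65 ± 0.19 (adjusted p = 0.042), the single call of 4 cytoskeleton probe sets over all and adjusted over the list alone. LOC100793686 and LOC100811201 fell by 2.58 ± 0.71 and 1.67 ± 0.47 (adjusted p = 0.0359 and 0.0419).

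Limma called 1306 probe sets at 72 h in Young, 1059 higher and 247 lower, 971 of them at least 2-fold. The 3′ to 5′ ratio of the actin control probe sets was 1.30 ± 0.29 with Al and 0.85 ± 0.08 without (log2, SD, n = 3 each), a difference of 0.45 without overlap. Its two-sided exact permutation p = 0.1 is the smallest that 3 against 3 allows. The same ratio of the glutathione transferase control went the other way, 1.33 ± 0.28 with Al and 1.96 ± 0.07 without (SD), also without overlap (two-sided exact permutation p = 0.1). The count was 287 without treated replicate 2, 523 without treated replicate 3, and 2139 without treated replicate 1. It was 659, 597 and 580 without untreated replicates 1, 2 and 3, 2480 with pairs as blocks, 2154 with runs of sample codes as blocks and 3183 in a fit on the compared groups alone. Of the 24 named calls 10 ended without treated replicate 2, 7 without treated replicate 3 and 7 without each untreated array. CHS1, HSF-01, IFS2, LOX7, LOC100793686, LOC100811201 and TUBB3 were lost in each of these, and CRK39, CYP93A1 and PTS1 without treated replicate 2 alone. Of the probe sets called higher, 557 were also called at 48 h in Young, against 26.1 by independence.

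**Figure D2:**
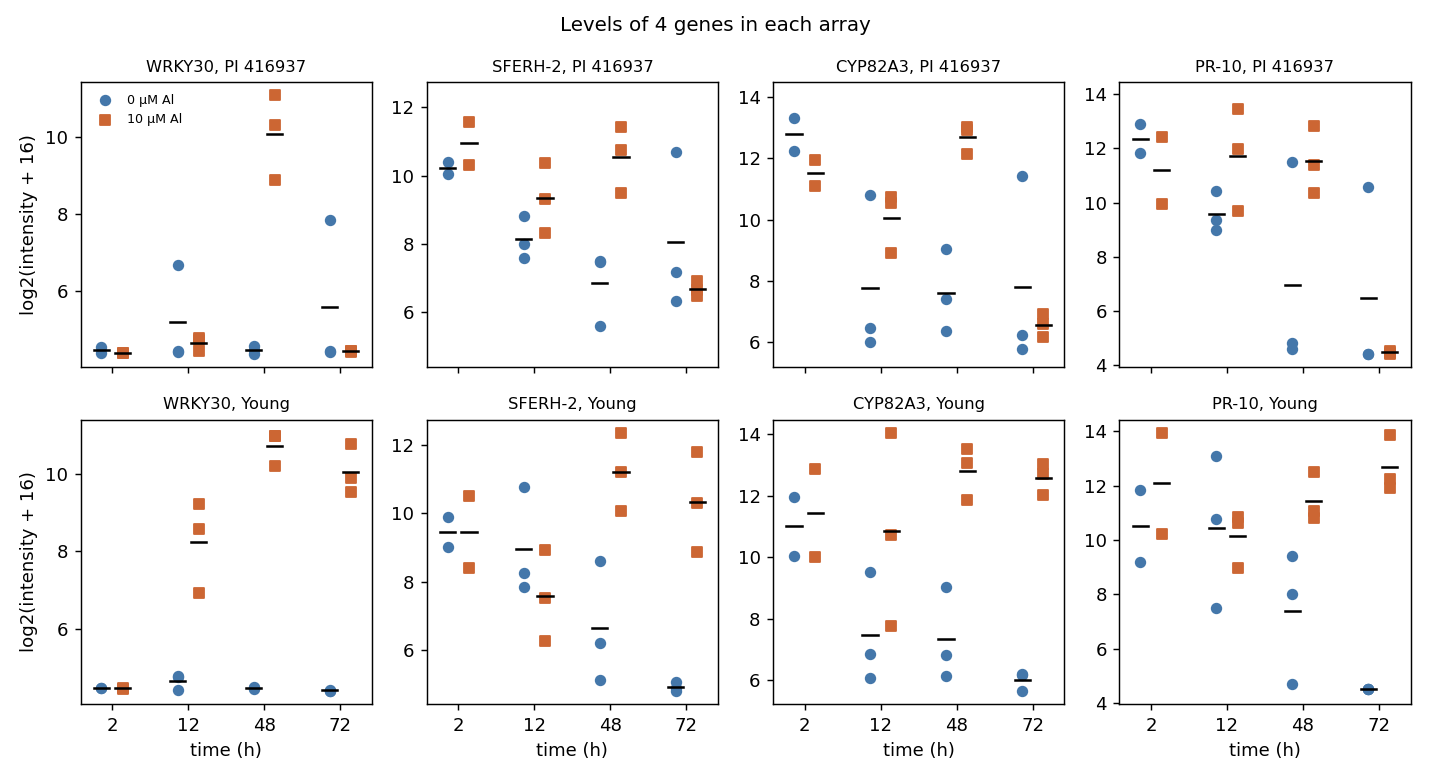
Points give log2(intensity + 16) of WRKY30, SFERH-2, CYP82A3 and PR-10 in each array against time in h, with circles for 0 µM Al, squares for 10 µM Al and bars for group means. At 72 h, mean PR-10 is 12.68 in treated and 4.51 in untreated Young roots, and in PI416937 untreated replicate 1 lies at 10.56 with each other untreated array at 4.43.

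As the mean of the 4 times in Young, LOC100809397 and LOC100306181 rose by 4.63 ± 0.74 and 4.47 ± 0.57 (adjusted p = 0.000125 and 7.85e-06). CYP82A3 and WRKY30 rose by 4.22 ± 0.74 and 3.88 ± 0.33 (adjusted p = 0.000345 and 2.47e-08). STOP1, a zinc-finger factor of proton and Al tolerance on chromosome 10 from 44808598 to 44811363, rose by 0.42 ± 0.11 (adjusted p = 0.015). It is the single measured member of the Al tolerance homolog list, called over all and adjusted over the list alone. The small heat shock protein HSP17.5-E rose by 1.73 ± 0.43 (adjusted p = 0.00944), and its 2 probe sets were the calls of 21 in the heat shock and chaperone list, over all and adjusted over the list alone. The list had a camera adjusted p = 0.000294, and adjusted p = 0.258 with an estimated correlation. LOC547819, a light-harvesting chlorophyll protein gene also named LHCP, and LOC100306554 fell by 1.64 ± 0.38 and 1.73 ± 0.41 (adjusted p = 0.00648 and 0.00645).

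Counted over the mean of the 4 times in Young, 55 WRKY, NAC and MYB probe sets were higher and 2 lower, or 64 and 4 adjusted over the list alone. Camera gave an adjusted p = 1.03e-09, and adjusted p = 0.252 with an estimated correlation. GST had 15 higher and 2 lower, or 21 and 2 adjusted over the list alone, with a camera adjusted p = 5.58e-09 and adjusted p = 0.252 with an estimated correlation. Of 7 pathogenesis-related probe sets, which belong to 4 genes, 5 were higher, over all and adjusted over the list alone. Camera gave an adjusted p = 1.96e-06, and adjusted p = 0.0743 with an estimated correlation. Phenylpropanoid and isoflavonoid probe sets had 6 higher, over all and adjusted over the list alone, with a camera adjusted p = 0.00074 and adjusted p = 0.258 with an estimated correlation. Limma called 2561 probe sets, 1782 higher and 779 lower, 920 of them at least 2-fold. STOP1 lost its call without untreated replicate 2 of 2 h and HSP17.5-E without treated replicate 1 of 2 h, at differences of 0.38 and 1.22.

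The difference in Al response between the genotypes was tested directly, as PI416937 minus Young. At 2 h the response of PI416937 was larger for LOC100794412 by 6.30 ± 0.60, for PIP2-8 by 4.06 ± 0.38 and for LOC100305692 by 4.21 ± 0.56 (adjusted p = 4.4e-08, 2.35e-08 and 3.54e-05). It was larger for LOC100305807 by 4.40 ± 0.99 (adjusted p = 0.0361). The difference for LOC100779173 was -1.11 ± 0.25 (adjusted p = 0.0362). PIP2-8 lay at 8.19 ± 1.39 (SD, n = 2) in treated PI416937, and group means of its probe set elsewhere lay between 4.36 and 4.61. It was the single call of 32 aquaporin probe sets, with 2 calls adjusted over the list alone, and its second probe set was not called over all. Limma called 126 probe sets, 105 higher and 21 lower, 82 of them at least 2-fold. A fit on the compared groups alone called 2 and ended all 5 named calls (adjusted p of up to 0.768). The count was 213 without untreated replicate 2 of Young, 290 without untreated replicate 1 of PI416937, 304 without treated replicate 2 of Young and 574 without treated replicate 1 of PI416937. LOC100794412, PIP2-8 and LOC100305692 kept their calls without each of the 8 arrays. Leaving out any single array ended the call of LOC100305807, of LOC100779173 or of both, with adjusted p of up to 0.28, and with pairs as blocks LOC100305807 was lost (adjusted p = 0.091).

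No difference in response passed the test at 12 h by limma, with 1228 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.235. WRKY30, called in Young at this time, is among the genes with 0 calls here. The count was 1 without treated replicate 2 of Young, 2 without treated replicate 2 of PI416937, 5 without treated replicate 1 of Young and 41 without treated replicate 3 of Young. It was 3 and 4 without untreated replicates 2 and 3 of Young.

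At 48 h the genotypes differed in few genes. The response of the methyltransferase gene SABATH2, on chromosome 2 from 4889156 to 4891510, differed by -5.10 ± 0.72 (adjusted p = 0.00257). With Al it lay at 9.87 ± 1.26 in Young and 4.72 ± 0.32 in PI416937, against 4.54 ± 0.01 and 4.49 ± 0.05 untreated (SD, n = 3 each). LOC547562, also named KNBS1, differed by 5.29 ± 0.96 (adjusted p = 0.0472) in 1 of 5 probe sets. That probe set lay at 9.90 ± 0.61 in treated PI416937, and its group means in Young lay between 4.40 and 4.57 at all times. Limma called 4 probe sets, 3 higher and 1 lower, 2 of them at least 2-fold. The other calls were 2 probe sets without an annotated gene, described after their values were seen, with 0.58 ± 0.09 and 0.66 ± 0.11 (adjusted p = 0.00257 and 0.0335). The count was 1 with pairs as blocks and 2 without treated replicate 1 or 2 of Young, untreated replicate 1 of Young or untreated replicate 2 of PI416937. It was 8 without treated replicate 3 of Young or untreated replicate 3 of PI416937, and 9 without treated replicate 3 of PI416937. LOC547562 lost its call without each of the 12 arrays except treated replicate 3 of PI416937, and with blocks (adjusted p = 0.202), and SABATH2 kept its call in all of these. A fit on the compared groups alone ended SABATH2 (adjusted p = 0.277) and kept LOC547562.

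Among the 4 times, 72 h had the highest count of differences in response. The 513 probe sets lower in this contrast had a median treated minus untreated difference of 2.72 in Young and -0.79 in PI416937, which was 0 without untreated replicate 1 of PI416937. The difference was -10.16 ± 2.26 for PR-10, -9.24 ± 0.95 for LOC100306414 and -6.81 ± 0.89 for WRKY30 (adjusted p = 0.0149, 3.1e-06 and 6.07e-05). It was -7.84 ± 1.73 for CYP82A2, -7.82 ± 1.89 for CYP82A3 and -6.58 ± 1.59 for GSTU47 (adjusted p = 0.0143, 0.025 and 0.025). It was -6.44 ± 1.31 for SFERH-2, -6.35 ± 0.71 for WRKY57 and -4.72 ± 0.83 for PR1-7 (adjusted p = 0.00721, 7.15e-06 and 0.00238). PTS1 and CRK39 differed by -5.39 ± 1.24 and -5.22 ± 1.24 (adjusted p = 0.0185 and 0.0232). The response was larger in PI416937 for LOC547630 and LOC100815084, by 2.22 ± 0.49 and 1.66 ± 0.32 (adjusted p = 0.0146 and 0.00566).

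By list, 0 WRKY, NAC and MYB probe sets were higher and 15 lower in this difference, or 0 and 26 adjusted over the list alone. GST had 0 higher and 5 lower, or 0 and 13 adjusted over the list alone, and pathogenesis-related probe sets 0 and 2, or 0 and 5 adjusted over the list alone. The P450 list had 0 higher and 6 lower, or 0 and 10 adjusted over the list alone. In the added list of ferritins and metal carriers 4 were lower, or 5 adjusted over the list alone. No camera test was planned for differences within a time.

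Limma called 605 probe sets in the 72 h difference, 92 higher and 513 lower, 534 of them at least 2-fold. Untreated replicate 1 of PI416937 lay apart from its group in the treated-root genes. Without it the count was 169, and PR-10, CYP82A2, CYP82A3, GSTU47, PTS1, CRK39 and LOC547630 lost their calls, 7 of the 13 named (adjusted p of up to 0.16). LOC100306414, WRKY30, WRKY57, SFERH-2, PR1-7 and LOC100815084 kept theirs without each array. The count was 198, 295 and 1073 without treated replicates 2, 3 and 1 of Young, and 366, 309 and 341 without untreated replicates 1, 2 and 3 of Young. It was 1031 without untreated replicate 3 of PI416937. Treated replicates 2 and 3 of Young ended 6 and 3 named calls, untreated replicates 1, 2 and 3 of Young ended 2, 4 and 3, and treated replicates 2 and 3 of PI416937 ended 3 and 1. A fit with pairs as blocks called 957. A fit on the compared groups alone called 114 and ended 9 of the 13 named calls, SFERH-2 and PR1-7 among them (adjusted p of up to 0.169).

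**Figure D3:**
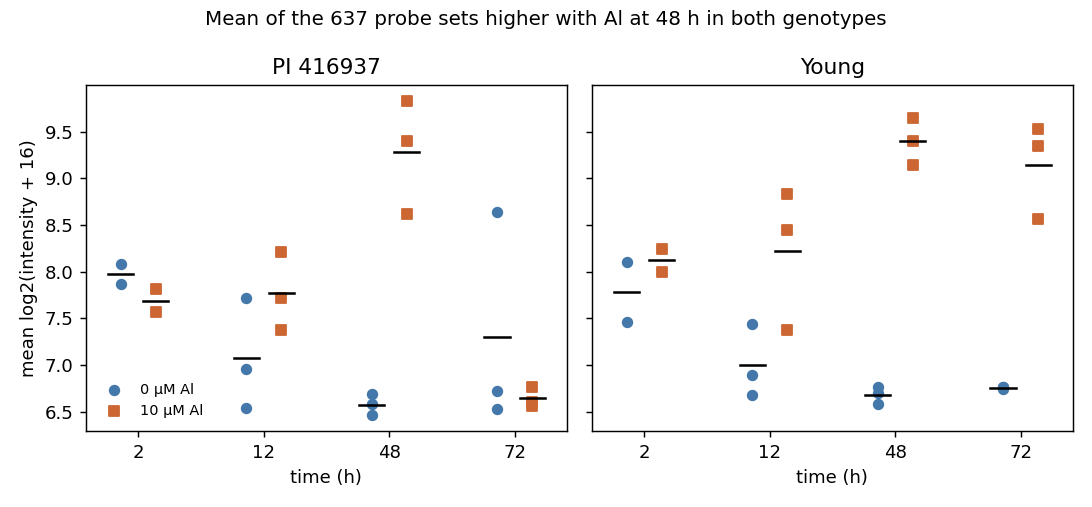
Points give the mean log2(intensity + 16) of the 637 probe sets called higher with Al at 48 h in both genotypes, per array, against time in h, with circles for 0 µM Al, squares for 10 µM Al and bars for group means. At 72 h treated arrays lie between 6.56 and 6.77 in PI416937 with a mean of 9.14 in Young, and untreated replicate 1 of PI416937 lies at 8.64; the 48 h values were used to choose the probe sets.

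As the mean of the 4 times, LOC100306414 and WRKY30 responded less in PI416937, by -3.23 ± 0.50 and -2.92 ± 0.47 (adjusted p = 0.00134 and 0.002). LOC100500487 and SABATH2 differed by -2.97 ± 0.59 and -2.58 ± 0.38 (adjusted p = 0.0184 and 0.000651). LOC100794412, LOC100799097 and PIP2-8 responded more in PI416937, by 1.52 ± 0.26, 1.07 ± 0.19 and 1.02 ± 0.16 (adjusted p = 0.00406, 0.00753 and 0.00159). The means of LOC100794412 and PIP2-8 rest mainly on the difference at 2 h (6.3 and 4.06), with 2 arrays per group. Of the 239 WRKY, NAC and MYB probe sets 0 were higher and 3 lower, or 4 and 15 adjusted over the list alone, with a camera adjusted p = 0.0443 and adjusted p = 0.637 with an estimated correlation. Of 32 aquaporin probe sets 1 was higher, over all and adjusted over the list alone, with a camera adjusted p = 0.000151 and adjusted p = 0.216 with an estimated correlation. Limma called 74 probe sets, 27 higher and 47 lower. Of the treated arrays, the count was 44 without replicate 2 of 72 h in Young, 153 without replicate 3 of 12 h in Young, 175 without replicate 2 of 2 h in Young and 458 without replicate 1 of 2 h in PI416937. Of the untreated arrays, it was 49 without replicate 3 of 12 h or replicate 1 of 72 h in Young, 128 without replicate 1 of 2 h in Young and 159 without replicate 1 of 2 h in PI416937. With pairs as blocks LOC100500487 lost its call (adjusted p = 0.0821).

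Untreated roots of the genotypes were compared as the mean of the 4 times, which asks for differences present without Al. A probe of 25 bases can lose signal to a sequence variant, so single probe sets are read here as signal. The isoflavone malonyltransferase gene IF7MaT, on chromosome 13 from 14452393 to 14454559, was higher in PI416937 by 5.09 ± 0.16 (adjusted p = 1.71e-20, n = 11 per genotype), but in 1 of 3 probe sets, the lowest of which differed by 0.29. LOC100527900 and LOC100500552 were higher by 3.89 ± 0.15 and 3.80 ± 0.15 (adjusted p = 3.59e-18 and 1.02e-17), and LOC100500059 differed by -4.94 ± 0.63 (adjusted p = 1.88e-06). Of 27 jasmonate and lipoxygenase probe sets 7 were higher and 1 lower, or 8 and 1 adjusted over the list alone. Camera gave an adjusted p = 0.012, and adjusted p = 0.935 with an estimated correlation. LOX9 was higher by 2.05 ± 0.37 in 4 of 5 probe sets, LOX7 by 1.23 ± 0.24 in 3 of 4, and LOX10 differed by -1.08 ± 0.30 (adjusted p = 0.00032, 0.000999 and 0.0316).

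Of 57 GST probe sets in untreated roots 1 was higher and 7 lower in PI416937, over all and adjusted over the list alone, with a camera adjusted p = 0.00135 and adjusted p = 0.935 with an estimated correlation. GSTU28, GSTU13 and GSTL3 differed by -1.86 ± 0.23, -1.07 ± 0.21 and -1.06 ± 0.26 (adjusted p = 9.9e-07, 0.00121 and 0.0117), with 2 of 4 GSTU13 and 3 of 3 GSTL3 probe sets called. GSTF5 was higher by 0.88 ± 0.20 (adjusted p = 0.00648) in 1 of 3 probe sets, the others at -0.30 and 0.36. Of 32 aquaporin probe sets 2 were higher and 1 lower, over all and adjusted over the list alone, with PIP2-1 higher by 2.23 ± 0.23 in 1 of 2 probe sets (adjusted p = 3.32e-08). The nodule marker list had 1 call of 2 over all and adjusted over the list alone, the uricase UR9 with -1.41 ± 0.27 (adjusted p = 0.000936). Limma called 1707 probe sets, 942 higher and 765 lower, 386 of them at least 2-fold. In the first 2 runs of sample codes alone the count was 640, and LOC100500059, LOX7, LOX9, LOX10, GSTU13, GSTL3, GSTF5 and UR9 lost their calls, 8 of 17 named here and among the other observations. LOX10 also lost its call without 10 single arrays.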

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

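Tests chosen only after the result was seen were those of a Young root or an exchanged array for the outlying array, and all those of the smaller response at 72 h and of the high scores at 2 h. The split tests were planned, as was the test for a root of 48 h.

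Differences in Al response between the genotypes, PI416937 minus Young, were found by the tested contrast of responses. At 2 h it called 126 probe sets, with LOC100794412 at 6.30, LOC100305807 at 4.40, LOC100305692 at 4.21, PIP2-8 at 4.06 and LOC100779173 at -1.11 log2 units. At 48 h it called 4, with LOC547562 at 5.29 and SABATH2 at -5.10. At 72 h it called 605, with PR-10 at -10.16, LOC100306414 at -9.24, CYP82A2 at -7.84, CYP82A3 at -7.82, WRKY30 at -6.81, GSTU47 at -6.58 and SFERH-2 at -6.44. WRKY57, PTS1, CRK39 and PR1-7 stood at -6.35, -5.39, -5.22 and -4.72, and LOC547630 and LOC100815084 at 2.22 and 1.66. The 72 h sizes include untreated replicate 1 of PI416937. PR-10 lay at 10.56 in it, against means of 4.43 in the other untreated and 4.48 in the treated PI416937 arrays. Without that array the 72 h count was 169 and 7 of the 13 named calls ended, those of PR-10, CYP82A2 and CYP82A3 among them. As the mean of the 4 times the contrast called 74, with LOC100306414 at -3.23, LOC100500487 at -2.97, WRKY30 at -2.92, SABATH2 at -2.58, LOC100794412 at 1.52, LOC100799097 at 1.07 and PIP2-8 at 1.02.

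For the mean of the 4 times, splits of the same arrays argue against chance for Al in Young (2561 real, highest other 335). In 1 of 100 splits, the real one included, as many were called. The same holds for the untreated genotypes (1707 real, highest other 917, 1 of 100). They do not exclude chance for Al in PI416937 (52 real, highest other 195, 12 of 100). For differences in response the splits cannot decide, as they exchange treated with untreated arrays and so break the Al response itself. As the mean of the 4 times the counts were 74 real and 48 highest other (1 of 100). At 48 h they were 4 and 2300 (19 of 100), and at 72 h 605 and 2445 (5 of 100). For the difference in response at 12 h the real count is 0, so all 100 splits reach it and the test decides nothing (highest other 331). The splits behind the highest values at 48 and 72 h exchanged 2 treated with 2 untreated arrays in PI416937 alone, at 72 h with untreated replicate 1 left in place. At 48 h this exchange mostly reversed a response that both genotypes share, which can by itself make a difference in response. Why the split at 72 h gave more calls was not tested.

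With 3 arrays against 3 only 10 splits exist, too few for a share under 0.05. In PI416937 the real count and the highest other were 1 and 28 at 12 h, 1425 and 86 at 48 h, and 14 and 68 at 72 h, with 9, 1 and 7 of the 10 splits as large. In Young they were 29 and 114 at 12 h, 979 and 2 at 48 h, and 1306 and 4 at 72 h, with 4, 1 and 1 of the 10 splits as large.

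The array of untreated PI416937 at 72 h, replicate 1, had a mean of 8.64 over the 637 probe sets called higher at 48 h in both genotypes, against 6.63 in the other untreated arrays. That the array holds a Young root sample is argued against by a genotype index of 1 over 24 probe sets, where Young is 0 and treated PI416937 arrays of 72 h lay between 0.92 and 0.993. Whether it holds a treated PI416937 root sample of 48 h cannot be told apart, as its time index of 1.06 lay among those of treated arrays of 72 h (0.858 to 1.17), yet single arrays of 48 h reached 0.845 with an SD of 0.748. An exchange with a treated PI416937 72 h array cannot be told apart either, as 3 treated arrays (6.56 to 6.77) lay within 1 log2 unit of the other untreated arrays, although the array lay at least 1.86 above each of them. A wrong label from elsewhere, or an untreated root under stress, may also explain the array, and neither was tested.

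At 72 h the response of PI416937 was smaller than that of Young in 513 probe sets with a median difference of -3.58, among them PR-10, WRKY30 and SFERH-2. The untreated array of replicate 1 alone is argued against as the whole cause, and so is a choice of probe sets on the 72 h arrays themselves, by the 637 probe sets chosen at 48 h. Without that array their median was -2.06 (quartiles -3.19 and -1.21) with all 637 below 0, while 138 of the 513 were still called. With all arrays, the median of the 637 was -2.6 before and -2.55 after quantile normalisation (quartiles -4.00 and -1.58 after). This argues against differences in signal distribution left by the authors' normalisation. A difference between the genotypes may explain the pattern as a hypothesis, untested, beside the separate runs of sample codes of the 72 h arrays.

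The 637 probe sets were also high in untreated roots at 2 h, with means of 7.98 in PI416937 and 7.78 in Young against 6.58 and 6.68 at 48 h. Within runs of sample codes the smallest of 4 differences of 2 h from 48 h was 0.76, but the 48 h arrays had chosen the probe sets. The 12 h arrays had chosen none. Within the same runs, untreated 2 h and 12 h arrays had 7.87 against 6.96 and 8.08 against 6.54 in PI416937. In Young they had 8.10 against 7.44 and 7.46 against 6.89. These values argue against a difference between runs as the whole cause. A choice of probe sets for low untreated values at 48 h is argued against by the difference of 2 h from 12 and 72 h, 0.9 in Young and 1.13 in PI416937. Of the set, 217 (34.1%) were over 1 log2 unit higher at 2 h than at 72 h in both genotypes, and 124 (19.5%) within 0.5. A response to transfer or handling might explain it, as might RNA quality, and neither was tested. The glutathione transferase 3′ to 5′ ratio was 0.98 and 0.35 in untreated PI416937 and Young roots at 2 h against 2.14 and 1.97 at 48 h. That of actin went the other way, 1.14 and 1.43 against 0.87 and 1.13.

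Probe sets of Phytophthora and Heterodera, which no comparison of soybean genes uses, gave calls of small size. Treated minus untreated calls in PI416937 numbered 14 at 2 h, 15 at 48 h, 35 at 72 h and 3 as the mean of the 4 times, with sizes of at most 0.11, 0.09, 0.21 and 0.03 log2 units. In Young they numbered 36 at 2 h, 1 at 12 h, 3 at 48 h, 158 at 72 h and 15 as the mean of the 4 times, with sizes of at most 0.34, 0.18, 0.07, 0.23 and 0.06. Of the 158, 152 were lower with a median of -0.01. At an unadjusted p under 0.05, 7139 were lower and 286 higher in Young at 72 h, and 5656 lower and 327 higher in PI416937 at 48 h.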

How the results depend on the processing

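Tests chosen only after the results were seen were the first 2 runs of sample codes alone, crossed pairs in PI416937 at 2 h and the rRNA controls. With pairs as blocks the counts that moved were 0 for PI416937 at 12 h, 7 at 72 h, 8 for Young at 12 h, 2480 at 72 h, and 1 and 957 for the differences in response at 48 and 72 h. With runs of sample codes as blocks they were 2 for PI416937 at 12 h, and 49 and 2154 for Young at 12 and 72 h. Without the variance trend they were 8 for PI416937 at 72 h, 23 for Young at 2 h and 2 for the difference in response at 48 h. A stricter filter gave 8 for PI416937 at 72 h and 24 for Young at 2 h. Quantile normalisation gave 0 for PI416937 at 12 h, 45 for Young at 12 h and 2 for the difference in response at 48 h. Log2(intensity + 1) gave 23 for Young at 2 h, and 1 and 2 for the differences in response at 12 and 48 h.

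Fits on the compared groups alone gave 0, 0, 246 and 0 calls in PI416937 at 2, 12, 48 and 72 h, 0, 0, 463 and 3183 in Young, and 2, 1 and 114 for the differences in response at 2, 48 and 72 h. These limma fits have few residual degrees of freedom. Array weights, whose estimation stopped before convergence, gave 129, 570, 6666 and 3063 in PI416937, 1006 as its mean, 319, 2462 and 8567 in Young at 12, 48 and 72 h, and 3969 as its mean. For the differences in response they gave 81, 30, 28 and 5433 at the 4 times and 132 as the mean, and for untreated roots 3311. The first 2 runs alone, as the mean of 2, 12 and 48 h, gave 640 for untreated roots and ended 8 of 17 named calls. The fit with runs as blocks used the same mean for untreated roots. At least 2-fold changed were 212, 0 and 4 in PI416937 at 2 h, 72 h and as the mean, 9 and 920 in Young at 2 h and as the mean, 82 and 2 in the difference in response at 2 and 48 h, and 386 in untreated roots. Camera with an estimated correlation gave 0 calls against 55, with 15 at an unadjusted p under 0.05. Without a filter, with crossed pairs and with rRNA controls no count moved by over 1.5 times, though crossed pairs ended 3 of 11 named calls of PI416937 at 2 h, MS among them (adjusted p of up to 0.0812).

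Leaving out 1 array at a time, where the lone array of a group at 2 h is assumed to vary like the other groups, gave 184 to 893, 0 to 91, 492 to 1626 and 20 to 68 calls in PI416937 at 2, 12, 48 and 72 h and 32 to 577 as its mean. In Young it gave 63 to 278, 2 to 969, 407 to 972 and 287 to 2139, and 1894 to 3785 as its mean. For the differences in response it gave 135 to 574, 0 to 41, 2 to 9 and 169 to 1073, and 44 to 458 as the mean. For untreated roots it gave 1388 to 2061. No named gene reversed in any alternative. Of 1824 calls of named genes without an array 296 ended, and of 154 calls 72 ended with the compared groups alone, 19 with pairs as blocks, 12 with log2(intensity + 1), 12 with at least 2-fold, 11 with array weights, 7 without the trend, 7 with runs as blocks, 4 without a filter, 2 with quantile normalisation and 2 with the stricter filter. The cause of these changes was not tested.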

Other observations

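Tests chosen only after the result was seen: the genes below follow the planned naming rule, but putting sugar transporters, GASA and glyoxalase genes together was chosen afterwards.

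As the mean of the 4 times, Al in Young also changed sugar transport and peptide genes. SWEET29 and SWEET34, sugar transporters, rose by 1.50 ± 0.33 and 0.94 ± 0.25, and SWEET17 fell by 1.02 ± 0.30 (adjusted p = 0.00413, 0.0176 and 0.0302, n = 11 per group). Of 7 SWEET probe sets 2 were higher and 1 lower, or 2 and 3 adjusted over the list alone. Of 19 probe sets of GASA genes, whose median of -0.06 and mean of 0.01 differ in sign, 2 were higher and 1 lower, or 4 and 1 adjusted over the list alone. GASA22 rose by 1.36 ± 0.37 and GASA13 fell by 0.93 ± 0.24 (adjusted p = 0.0199 and 0.0131). Glyoxalases detoxify methylglyoxal, and of 13 of their probe sets 1 was higher and 2 lower, or 1 and 5 adjusted over the list alone. GLYI-19 rose by 1.73 ± 0.50, and GLYI-6 and GLYII-5 fell by 0.48 ± 0.15 and 0.28 ± 0.08 (adjusted p = 0.0287, 0.0476 and 0.0319). Leaving out treated replicate 1 of 2 h ended 6 of the 16 calls named for this mean and untreated replicate 2 of 2 h ended 5, with 16 other arrays ending 1 to 3 each. With pairs as blocks GLYI-6 lost its call (adjusted p = 0.0686).

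In untreated roots the genotypes also differed in regulators and a phosphatase. The transcription factor gene BZIP94 was higher in PI416937 by 2.37 ± 0.18 in 1 probe set and by 1.39 in its other (adjusted p = 2.59e-11 and 6.19e-09, n = 11 per genotype). Of 94 bZIP probe sets 4 were higher and 2 lower, over all and adjusted over the list alone. SEOM, a sieve element occlusion gene, was higher by 1.65 ± 0.18 (adjusted p = 1.45e-07), the single call of 9 probe sets of its list, over all and adjusted over the list alone. The calcium-dependent kinase CDPK-BETA was higher by 1.33 ± 0.18 (adjusted p = 6.82e-06), with 1 of 18 calmodulin and kinase probe sets higher and 3 lower, over all and adjusted over the list alone, a median of -0.06 and a mean of 0.01. The purple acid phosphatase PAP25 differed by -1.01 ± 0.13 in 3 of 3 probe sets (adjusted p = 2.14e-06), the 3 lower calls of 22 in the added phosphate list, with 1 higher, over all and adjusted over the list alone. These calls held in the first 2 runs of sample codes alone.

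In the fixed lists for seed storage, auxin, iron and metal, and starvation for phosphate, 0 probe sets were called by limma in any of the 16 comparisons. These lists held only 2, 1, 3 and 2 tested probe sets, so they cannot speak for such genes in general. In the added lists, the ferritin SFERH-2 and the phosphatase PAP25 were called, as given above. Of 319 probe sets higher at 2 h in PI416937, 4 were also called higher at 48 h, fewer than the 10.8 by independence (two-sided Fisher's exact p = 0.0287). The set called higher at 48 h in both genotypes already had a mean of 7.98 in untreated PI416937 at 2 h, against 6.58 at 48 h. Why few were shared was not tested. Of 25 called higher at 12 h in Young, 13 were also called at 48 h, against 0.616 by independence (two-sided Fisher's exact p = 4.44e-15). Both tests count probe sets that change together, and several of a gene, as independent, so their p can be far too small.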
